A study of Mus musculus and synthetic construct with 13 samples.

How the data were processed

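Guide abundance was measured by sequencing in 13 libraries from immortalised bone-marrow-derived macrophages of the mouse with Cas9 and an NF-kB reporter of GFP. Per the labels' protocols, cells were transduced at a multiplicity of infection below 0.3 and selected with puromycin at 10 ug/mL. Clonal lines 1 to 3 each gave a day 0, a day 14, a GFP-high and a GFP-low library, and the pooled plasmid gave 1. The gates held the brightest and dimmest 20% after 24 h with 200 ng/mL Pam3CSK4. Per the labels, coverage in cells per guide was 2000 in culture, 1000 at day 14 and 100 at sorting.

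The deposited guide table holds counts, whole numbers of reads per guide without normalisation, which the authors made with MAGeCK (version not given) from 23-nucleotide reads with 1 base trimmed at the 5-prime end and a guide length of 19, per the submitters' processing notes. The notes name the mouse build mm39 for the guides. The second deposited table is of the kind other, text that names each guide, its spacer sequence and its target. It was read without a header, and it has no column of guide efficiency. Of 39748 spacers listed, 39747 have 19 bases. Target classes were read from the target names (uORF, ncORF, dORF, other ORF, noncoding for lncRNA regions, and CDS for plain gene names). Of 1225 CDS names, 1211 are symbols in the RefSeq annotation of GRCm38.p6, which served for names alone. Genomic positions of guides were not used here.

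Libraries held 9.81 to 32.8 M reads, and all libraries but day 14 of clone 2 held more than 20 M. Guides with fewer than 10 reads in the plasmid pool (17) were left out, and targets with at least 4 guides were tested (4210). Guide counts were summed over each target. Libraries were scaled by the median ratio over the 1500 non-targeting guides. Log2 ratios within clones used a pseudocount of 1. Counts for targets that share guides under a joint name were kept under that joint name.

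The comparisons were day 14 against day 0 and GFP-high against GFP-low, each with 3 libraries per group, n = 3. The test fixed for both was edgeR's quasi-likelihood F test with group alone in the model, adjusted by Benjamini and Hochberg over all targets, at a threshold of 0.05. Single guides were tested in the same way. Pairs of a noncanonical ORF with the CDS or the lncRNA of its gene were tested with limma on the difference of log2 scaled counts within libraries. Class shares were compared with Fisher's exact test, 2-sided. Gene lists were tested with fry and with camera, at a preset correlation of 0.01 and with an estimated one, on CDS targets. A member count adjusted over the list alone means Benjamini-Hochberg over the members of that list. Correlations across genes had a permutation p from 100000 resamples, the smallest of which is 1.0e-05. The plasmid pool has no replicate, so day 0 was set against it as values and as ranks among 10000 random gene lists, without a test.

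The replicates are clonal lines, so p-values measure the spread between clones. The same numbered clone gave all 4 of its cell libraries, which pairs them. Deviations of targets from their group mean correlated within clones at 0.456, 0.449 and 0.647 for day 14 with day 0 and at 0.818, 0.861 and 0.925 for the gates, and at most at 0.375 and 0.557 between different clones. A fit with the clone as a block was therefore given beside each result whose call or count it changed.

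Rank aggregation followed the robust rank aggregation idea of MAGeCK and was written for this work. It ranks guides by their p-value in edgeR and scores whether a target's guides rank together. Its p comes from 100000 sets of random ranks, so that it measures agreement among guides rather than among clones. These ranks were drawn as independent, so p may be too small where the spacers of a target overlap. Targets at the smallest p that the sets allow share 1 adjusted p, which does not rank them. The maximum likelihood procedure of MAGeCK was not run here. Alternatives also covered scaling (TMM, DESeq2 size factors, total counts, guides of noncanonical ORFs), DESeq2's Wald test, all 12 cell libraries in 1 fit, no plasmid filter or a minimum of 50 plasmid reads, at least 6 guides per target, fry, medians, means or random non-targeting sets in place of summed counts, removal of each target's most extreme guide, and removal of each clone and each library. The tests, these alternatives, the gene lists and the rule for naming targets were fixed before the data were examined. Combinations of the block or of rank aggregation with a second choice were added later.

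The naming rule took, per comparison, the 8 lowest and 8 highest targets of each of CDS and noncanonical classes that passed the threshold and moved the same way in all 3 clones, or the 2 with the smallest p where none passed. It added up to 4 members per gene list, every measured member of the TLR2 and NF-kB inhibitor lists, and 3 pairs per kind. Since the fixed test called 2 and 0 targets, the same rule was applied, after the data were seen, to calls with the clone block and by rank aggregation. The 2 lncRNA targets given as examples of the excess in clone 2 were chosen after their values were seen. The methods were tested on simulated counts with 50 changed targets at each of 4 log2 folds. For day 14 the fixed test recovered 44, 32, 31 and 48 of 50 at log2 folds of -2, -1, 1 and 2 with 0 false calls, and rank aggregation 48, 43, 46 and 50 with 0 false calls. The blocked edgeR fit for day 14 recovered 50, 48, 50 and 50 with 8 false calls. Between the gates rank aggregation recovered 49, 35, 36 and 49 with 2 false calls. Counts were drawn from each clone's own means with guide dispersions of the blocked fit, which favours tests with the block. Each simulated change was the same for all guides of a target and in all 3 clones. Guides or clones that disagree, or an excess of guides in 1 library, were not simulated, so these rates do not cover them.

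The computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package, version 1.17.8.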

Results

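The screen measured guide RNA abundance in immortalised mouse bone-marrow-derived macrophages, a macrophage line that grows without limit in culture. The cells carried Cas9, the nuclease that cuts DNA where a guide RNA directs it, and a green fluorescent protein (GFP) gene switched on by the transcription factor NF-kB. The guide table listed 39748 guides. They covered 1225 canonical coding sequences (CDS), 3663 targets made of noncanonical open reading frames (ORFs), 1345 targets in long noncoding RNA (lncRNA) loci outside such ORFs, and 1500 non-targeting guides that match no mouse locus by design. Noncanonical ORFs were named in the table as upstream ORFs of a host gene (uORF, 2336 targets), ORFs on noncoding transcripts (ncORF, 1187), downstream ORFs (dORF, 73) and other ORFs (67).

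The 13 libraries were 1 plasmid pool and 4 cell populations from each of 3 clonal lines. The populations were day 0, taken after drug selection, day 14 of growth, and the brightest and dimmest 20% of cells sorted after 24 h with 200 ng/mL Pam3CSK4 (GFP-high and GFP-low). Cells were transduced at day -10 and selection began at day -7, so guides could act before day 0. Pam3CSK4 is a synthetic lipopeptide that activates the TLR1/TLR2 receptor pair. Libraries held between 9.81 M reads (day 14, clone 2) and 32.8 M reads (plasmid pool), a mean of 247 to 824 reads per guide. Guides without a read made up 0.0377% of the table in the plasmid pool and at most 2.55%, in GFP-low of clone 3. After filtering, 4210 targets were tested, 1224 of them CDS and 2091 noncanonical ORFs. Values below are log2 ratios of control-scaled counts within each clone, given as mean ± SD over n = 3 clones.

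Before day 0, guides against genes that all dividing cells use had already been lost from the pool. The median log2 ratio of day 0 to the plasmid pool over 11 ribosomal protein genes was -4.05 in clone 1, -4.16 in clone 2 and -5.63 in clone 3. Over 7 splicing genes it was -2.87, -2.92 and -4.26. Both medians were lower than those of all 10000 random gene lists of the same size. Over 2 proteasome genes the medians were -3.26, -3.64 and -8.44, and over 8 translation factors -1.19, -1.08 and -2.64. Mitochondrial respiration genes (12) had -1.07, -1.08 and -2.45, DNA replication and cell division genes (3) -1.58, -1.80 and -2.29, and transcription co-activators (4) -1.20, -0.91 and -2.51. Among the random lists, division genes lay at percentiles 2.17, 1.59 and 4.41 and co-activators at 4.27, 8.52 and 2.54. Random lists as small as these thus reached such medians at times. Proteasome, translation and respiration genes lay at percentile 0.88 or lower in each clone. Lists for signalling, macrophage identity and growth suppression had medians between -0.50 and 0.04 in each clone. Log2 ratios were below -1 in all 3 clones for 190 of 1224 CDS targets (15.5%), 3 of 1322 uORF targets and 7 of 895 lncRNA region targets, and for 0 of 680 ncORF and 0 of 48 dORF targets. The plasmid pool was a single library, so these are values without a test.

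**Figure D1:**
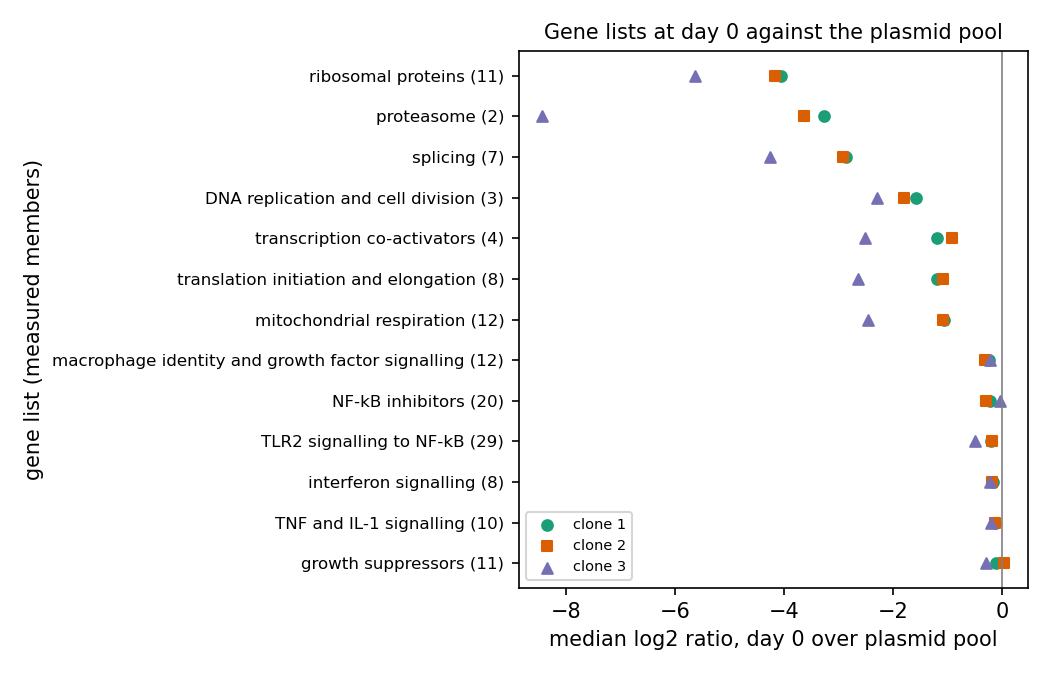
Median log2 ratio of day 0 over the plasmid pool (x axis) for the members of each gene list (y axis, measured members in parentheses), 1 point per clone. Ribosomal protein, proteasome and splicing genes lie lowest, at medians from -2.87 to -8.44, while signalling lists stay near 0.

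The comparison of day 14 with day 0 asked which targets the macrophages needed for, or were held back by during, 14 days of growth. Guides against Pcgf1 and Kdm2b rose in all 3 clones. Both genes encode subunits of a variant Polycomb repressive complex (PRC1.1), which marks chromatin for gene silencing. Pcgf1 had a log2 ratio of 1.74 ± 0.21 and Kdm2b of 1.15 ± 0.31, with 6 of 6 guides higher for each. These were the only targets of 4210 past the threshold in edgeR's quasi-likelihood test (adjusted p = 0.0291 and 0.0441), and 0 targets passed it as lower. At an unadjusted p under 0.05 the test gave 214 targets, and DESeq2 called 69 (8 higher, 61 lower). With the clone as a block, 1 target was called, Pcgf1 (adjusted p = 0.00357), and Kdm2b missed the threshold (adjusted p = 0.0508). The count went to 0 without clone 1 or without clone 2, and to 73 without clone 3.

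Rank aggregation, which asks whether the guides of a target rank together rather than whether clones differ by more than their spread, called 187 targets, 130 lower and 57 higher. The largest falls among them were in Ppp4c, the catalytic subunit of protein phosphatase 4 (-4.80 ± 0.58), Kcnk13, a potassium channel (-3.35 ± 1.59), Pcif1, which methylates mRNA caps (-3.31 ± 0.59), and Spi1, the transcription factor PU.1 that macrophages depend on (-3.13 ± 0.49). Ppcs, an enzyme of coenzyme A synthesis (-3.02 ± 1.89), the tubulin gene Tubb5 (-2.95 ± 1.14), the poly(A)-binding protein gene Pabpc1 (-2.82 ± 1.10) and Men1, the histone methyltransferase cofactor menin (-2.77 ± 0.64), fell as well. All 6 guides were lower for each of these 8 genes, with adjusted p between 0.0014 and 0.00526. None of the 8 passed edgeR's test (adjusted p 0.328 to 0.789), nor the blocked edgeR fit, where Ppp4c, Pcif1 and Men1 had an adjusted p of 0.0508. With the clone block in rank aggregation, 135 targets were called, 110 lower (86 of them shared) and 25 higher (20 shared), and Spi1 and Ppcs were no longer among them (adjusted p = 0.415 and 0.122). The 8 differed in the reads left at day 0, with control-scaled reads over 6 guides of 186 ± 182 (Spi1), 296 ± 238 (Ppp4c), 363 ± 263 (Tubb5), 403 ± 334 (Ppcs), 405 ± 192 (Pabpc1), 664 ± 528 (Kcnk13), 1008 ± 569 (Pcif1) and 1419 ± 206 (Men1), so falls on few reads are less certain.

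Guides against 2 promoters of cell death rose with those of the Polycomb genes by rank aggregation. Bbc3, which encodes PUMA, stood at 1.57 ± 0.63 and Bcl2l11, which encodes BIM, at 0.90 ± 0.28 (adjusted p = 0.0014 for each). Other targets shared this adjusted p, which is limited by the number of random sets and does not rank them. Rasa3, an inhibitor of Ras family GTPases (0.98 ± 0.74), the zinc finger gene Zfp91 (0.95 ± 0.47) and the RNA-binding protein gene Rbm47 (0.79 ± 0.46) also rose, as did 1 CDS listed without a gene symbol (0.67 ± 0.54). None of these 6 passed edgeR's test, with or without the clone block.

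**Figure D2:**
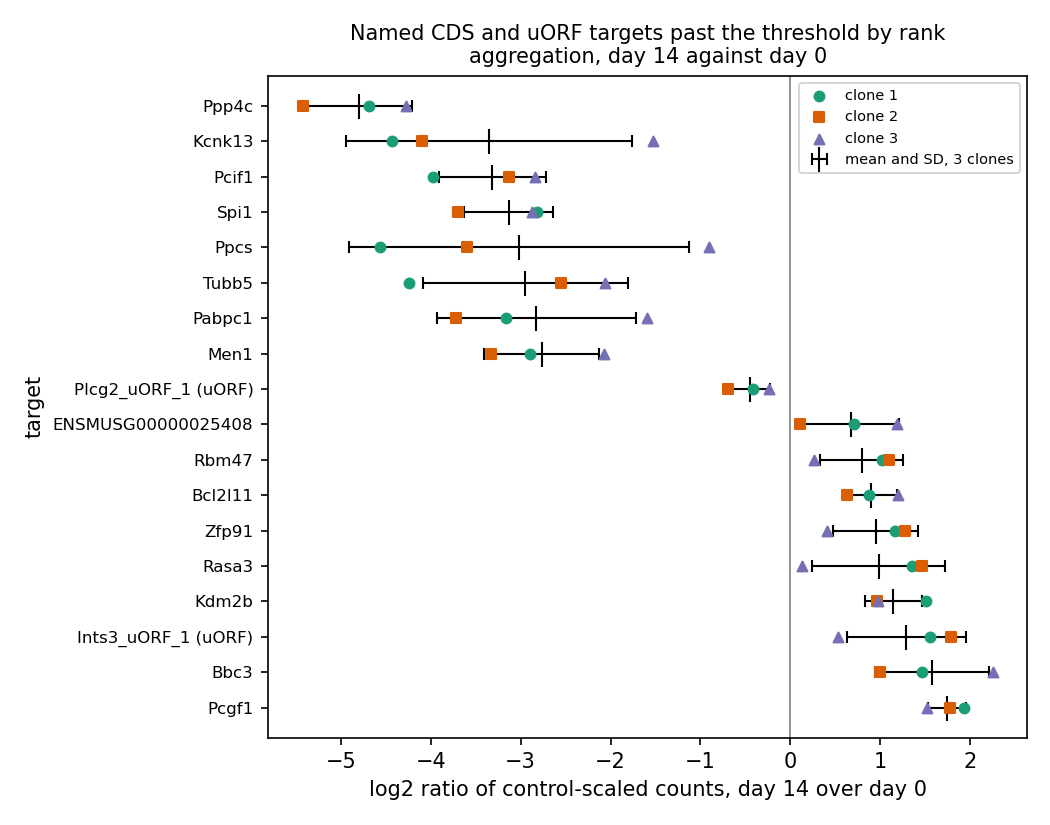
Log2 ratio of control-scaled counts, day 14 over day 0 (x axis), for the named CDS and uORF targets past the threshold by rank aggregation (y axis). Points are the 3 clones and bars the mean ± SD; the label Ints3_uORF_1 stands for a target covering uORFs 1 and 2. Ppp4c lies lowest at -4.80 and Pcgf1 highest at 1.74.

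Targets whose guides fell over 14 days were almost all canonical coding sequences. By rank aggregation 128 of 1224 CDS targets fell (10.5%), 117 of them in all 3 clones, against 1 of 2091 noncanonical ORF targets (0.0478%; Fisher's exact test, 2-sided, adjusted p = 2.57e-55) and 1 of 895 lncRNA regions. The noncanonical ORF was Plcg2_uORF_1, upstream of the phospholipase C gamma 2 coding sequence, at -0.45 ± 0.23 with 5 of 6 guides lower (adjusted p = 0.00556, and 0.0380 with the clone block). The lncRNA region was Mef2a_noncoding at -0.47 ± 0.10 (adjusted p = 0.0101, and 0.138 with the clone block). By edgeR's test 0 targets fell in any class, so that no class difference could show there. Guide sets differed between classes, since 1221 of 1224 CDS but 772 of 1322 uORF targets had at least 6 guides. The classes were not matched for guide number or position, so the difference in shares cannot be laid to the class alone. Fisher's test here counts targets and not clones.

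Among noncanonical targets that rose, the joint target of Ints3 uORFs 1 and 2 had the largest change, 1.29 ± 0.67, with 6 of 6 guides higher (rank aggregation, adjusted p = 0.0014, and 0.00132 with the clone block; edgeR, adjusted p = 0.702). Ints3 encodes a subunit of the Integrator and single-strand DNA sensor complexes. All 6 spacers of this target overlap one another and join into 1 stretch of 26 bases, CACCATGGCCGCCTCTGTGTGGTGTG, so they address 1 short site. Rank aggregation takes guides as independent, so its p for this Ints3 target may be too small. It also called 34 lncRNA loci higher, 23 ncORF and 11 region targets. With the clone block rank aggregation called 1 lncRNA target higher, and without clone 2 it called 0. In the day 14 library of clone 2, 803 of 20453 lncRNA guides (3.93%) lay more than 1.5 log2 units above day 0, against 22 in clone 1, 80 in clone 3, and 62 of 9808 uORF guides (0.632%) in clone 2 itself. The named examples were 2900076A07Rik_ncORF_1, at 1.64 in clone 2 and 0.02 and 0.24 in clones 1 and 3, and 2210408F21Rik_ncORF_1, at 1.10, 0.02 and 0.37 in the same order.

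**Figure D3:**
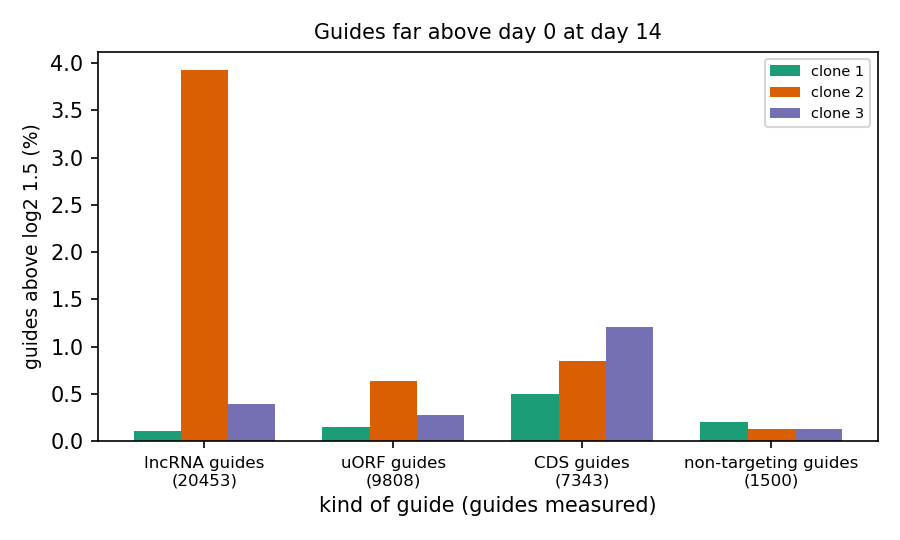
Percent of guides more than 1.5 log2 units above day 0 at day 14 (y axis) for 4 kinds of guide (x axis, number measured in parentheses), 1 bar per clone. Clone 2 reaches 3.93% among lncRNA guides, against 0.108% in clone 1 and 0.391% in clone 3.

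Members of several fixed gene lists fell by day 14. By rank aggregation 4 of 12 mitochondrial respiration genes fell, among them Uqcrq of respiratory complex III (-1.55 ± 0.87) and the mitochondrial ribosome gene Mrpl42 (-0.80 ± 0.71), and 8 were called when adjusted over the list alone. In the block rank aggregation also called 4, of which Uqcrq alone was among the unblocked calls, and Mrpl42 missed the threshold (adjusted p = 0.160). Of 8 translation factors, 2 fell, the cap-binding protein gene Eif4e2 (-1.47 ± 0.63) and Eif5 (-1.45 ± 0.82), with 4 called when adjusted over the list alone, and Eif5 missed the threshold with the clone block (adjusted p = 0.739). Of 4 transcription co-activators, 2 fell, the histone acetyltransferases Ep300 (-1.49 ± 0.77) and Crebbp (-1.49 ± 0.44), and 4 adjusted over the list alone. The mitotic checkpoint gene Bub1b (-1.17, -1.62 and -0.20 in clones 1 to 3) was the 1 of 3 division genes that fell, and 1 was called when adjusted over the list alone, but 0 with the clone block (Bub1b, adjusted p = 0.106). Of 12 macrophage identity and growth factor genes, 2 fell, Spi1 and the survival gene Bcl2l1 (-1.71 ± 1.12), and 2 when adjusted over the list alone, with Bcl2l1 alone called in the block. Of 11 growth suppressors, 2 rose, Bbc3 and Dusp6 (1.16, 1.47 and -0.70 in clones 1 to 3, so in 2 of 3), and Atm, the DNA damage kinase, fell (-0.96 ± 0.11), with 3 called when adjusted over the list alone. Of 29 genes of TLR2 signalling, 4 fell, Syk (-2.15 ± 1.47), Ikbkb (-1.41 ± 0.32), Ube2n (-1.28 ± 0.66) and Traf6 (-1.06 ± 0.32), and 4 when adjusted over the list alone, and Ube2n missed the threshold with the clone block (adjusted p = 0.149).

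Ribosomal protein genes (11), splicing genes (7), proteasome genes (2), the RNA polymerase gene Polr1d, NF-kB inhibitors (20), TNF and IL-1 signalling (10) and interferon signalling (8) had 0 calls by rank aggregation, and 0, 2, 0, 0, 0, 0 and 0 when adjusted over the list alone. Blocked rank aggregation called Traf2 of the NF-kB inhibitors as lower (-0.58 ± 1.11, adjusted p = 0.0104). Ribosomal protein genes had a median log2 fold change of -1.94 on the few reads left at day 0. By edgeR's test each list had 0 members past the threshold, and adjusted over the list alone 1 in each of growth suppressors, macrophage identity, TLR2 signalling and co-activators. With the clone block, the counts adjusted over the list alone were 7 mitochondrial respiration, 3 co-activator and 1 translation factor genes, and 2 each of ribosomal protein, growth suppressor, macrophage identity and TLR2 genes. Fry, a set test on the same edgeR fit, called 0 of 13 lists (1 at an unadjusted p under 0.05), and with the clone block it called DNA replication and cell division as lower (adjusted p = 0.0278), a call lost with TMM scaling (0.100) and in camera (adjusted p = 0.519 with an estimated correlation). Without clone 3 fry called 9 lists, and camera with an estimated correlation called 0 (lowest adjusted p = 0.317). At its preset correlation camera then called mitochondrial respiration (adjusted p = 0.00662), ribosomal proteins, co-activators (0.00930 for each) and splicing (0.0229) as lower. It called growth suppressors as higher (adjusted p = 0.0229). With all 3 clones camera at its preset correlation called ribosomal proteins (adjusted p = 0.00176), mitochondrial respiration and co-activators (0.0458 for each) as lower. None of these lists held with an estimated correlation (adjusted p = 0.516 for each). Aminoacyl-tRNA synthetases and reporter controls had 0 measured members.

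Where a gene carried both a uORF target and a CDS target, the 2 could be set against each other within libraries. At day 14 the CDS guides of Supt20, a subunit of the SAGA co-activator (-2.32 ± 0.21), fell relative to those of its uORFs (0.03 ± 0.18), a difference of 2.35 on the log2 scale. For Ppp2r2a, a regulatory subunit of protein phosphatase 2A, the values were -2.66 ± 0.82 and -0.10 ± 0.09, and for Men1 -2.77 ± 0.64 and 0.03 ± 0.33. Limma called 7 of 1325 such pairs (adjusted p = 0.0335 for each of these 3), and 135 with the clone block, all but 3 of them with the noncanonical ORF above the CDS, and on simulated counts the blocked test recovered all but 1 of 124 changed pairs with 16 false calls. The count was 0 without clone 1 or clone 2 and 219 without clone 3. Of 596 pairs of an ORF with the rest of the same lncRNA, limma called 0 (5 at an unadjusted p under 0.05), and the smallest p was that of Rab26os_ncORF_3 (0.70 ± 0.33 against -0.05 ± 0.14, adjusted p = 1.00). Across pairs, the log2 fold changes of the ORFs correlated weakly with the CDS (Pearson r = 0.150, Spearman rho = 0.113, permutation adjusted p = 2.0e-05 and 1.8e-04) and with the lncRNA (r = 0.149, rho = 0.168, adjusted p = 3.6e-04 and 1.8e-04). The relation with the lncRNA was not detected without clone 2 (r = 0.0507, rho = 0.0102, adjusted p = 0.236 and 0.878), the clone with the excess of lncRNA guides, while that with the CDS stayed past the threshold by r (0.0952, adjusted p = 0.00118) and not by rho (0.0576, adjusted p = 0.0731). These are correlations across pairs, 1 per ORF target, so the CDS or lncRNA of a gene with several ORF targets enters several times. Pairs are thus not independent replicates, and the permutation p-values, which treat them as such, may be too small. In all, 4 relations were computed, then 12 with 1 clone left out.

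The comparison of the gates asked which targets the macrophages needed to switch on, or to restrain, the NF-kB reporter after TLR2 was engaged. Of 29 measured genes of TLR2 signalling, 10 fell in the bright cells with the clone as a block, while the list as a set missed the threshold by fry in that fit (adjusted p = 0.0529). Guides against Tlr2, the receptor subunit that binds Pam3CSK4, fell by 3.68 ± 0.21 in GFP-high against GFP-low. Guides against the NF-kB subunit gene Rela (-3.57 ± 0.67), the kinase gene Irak4 (-3.53 ± 0.82) and Myd88, the adaptor that joins the receptor to Irak4 (-3.06 ± 0.21), fell to a similar extent. Nfkb1 (-2.32 ± 0.52), the I-kappa-B kinase gene Chuk (-2.15 ± 0.36), Irak1 (-1.89 ± 0.90), the ubiquitin ligase gene Traf6 (-1.85 ± 0.55), Irak2 (-1.13 ± 0.61) and Tlr1 (-0.93 ± 0.18) followed. Each of these 10 genes was lower in 3 of 3 clones with 6 of 6 guides lower, at an adjusted p from 1.26e-06 (Tlr2) to 0.0261 (Irak2) in edgeR's blocked fit and 0.00272 by rank aggregation. The latter is the smallest value that unblocked rank aggregation could give between the gates, so targets at 0.00272 are tied and not ranked by it.

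The unblocked edgeR test fixed as the main one called 0 of 4210 targets between the gates, and 17 lay at an unadjusted p under 0.05. DESeq2 called 7 (1 higher, 6 lower), edgeR with the clone block 30 (10 higher, 20 lower), and rank aggregation 60 (38 higher, 22 lower), or 45 in the block (23 higher, 22 lower), of which 12 of the higher and 19 of the lower calls were shared. The excess of higher calls was thus not kept in the block, and of 35 higher CDS calls by unblocked rank aggregation 21 were higher in all 3 clones. Of the blocked calls, 18 of the lower and 8 of the higher ones were also rank aggregation calls. On counts simulated for this comparison the unblocked test recovered 0 of 50 targets at each of the 4 log2 folds -2, -1, 1 and 2, and the blocked fit 50, 46, 48 and 49, with 8 false calls among 4210 targets. These counts were drawn from each clone's own means with guide dispersions of the blocked fit, so the simulation favours the block. Clones that disagree were not simulated, so these rates do not vouch for the blocked calls on the real counts. Blocked counts were 17 without clone 1, 70 without clone 2 and 90 without clone 3. Non-targeting guides were spread most widely in clone 3, where the SD of their log2 ratio to day 14 was 1.40 in GFP-high and 1.55 in GFP-low, against 0.35 to 0.61 in the other clones.

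Of 29 measured members of the TLR2 list, 10 fell with the clone block, 11 fell by rank aggregation (Ikbkb in addition, -1.14 ± 0.41, adjusted p = 0.0140, and 0.465 with the clone block) and 17 were not called by the latter. The NF-kB subunit gene Rel rose by rank aggregation (0.67 ± 0.29, adjusted p = 0.00272) and missed the threshold with the clone block (adjusted p = 0.25). Adjusted over the list alone, 5 members were called by the unblocked edgeR test, 16 with the block and 13 by rank aggregation. As a set the list fell by fry (adjusted p = 0.0156) and by camera (adjusted p = 4.53e-26 with the preset and 0.00308 with an estimated correlation). With the clone block fry gave an adjusted p of 0.0529, and camera 7.31e-30 with the preset but 0.100 with an estimated correlation. With the block and TMM scaling together fry called this list lower and NF-kB inhibitors and interferon signalling higher (adjusted p = 0.0428 each). Camera with an estimated correlation then called none of the 3 (adjusted p = 0.133, 0.184 and 0.294). Unblocked, fry called 0 lists when any 1 clone was left out, and with TMM scaling over all targets it called interferon signalling as higher and growth suppressors as lower (adjusted p = 0.0148 and 0.0199) but not this list (0.109). Camera with TMM scaling and an estimated correlation ran the other way. It called the TLR2 list (adjusted p = 0.0229), and not interferon signalling or growth suppressors (0.0560 and 0.434). At its preset correlation camera called the TLR2 list as lower (adjusted p = 4.81e-26) and interferon signalling as higher (1.63e-05), and not growth suppressors (0.191). Members with no call in any of the 3 tests included Tirap (-0.61 ± 0.39), Ikbkg (-0.60 ± 1.60), Cd14 (-0.60 ± 0.84), Map3k7 (-0.20 ± 0.82), Cd36 (-0.11 ± 0.13), Tab1 (-0.49 ± 0.70), Tab2 (0.53 ± 0.49), Tab3 (0.01 ± 0.57) and Nfkb2 (0.18 ± 0.22). The remaining members were Rbck1 (-0.78 ± 0.53), Syk (-0.69 ± 0.39), Malt1 (-0.54 ± 0.40), Relb (-0.39 ± 0.17), Bcl10 (-0.16 ± 0.42), Ube2v1 (0.05 ± 0.30), Btk (0.08 ± 0.26) and Ube2n (0.23 ± 0.91). Outside the list, guides against the transcription factor gene Irf2 fell in the bright cells (-2.35 ± 0.38, blocked adjusted p = 5.29e-05).

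Guides against 4 of 20 measured NF-kB inhibitors were enriched in the bright cells with the clone block. Tank, an adaptor of the kinases TBK1 and IKK-epsilon, rose by 2.05 ± 0.35, Traf3 by 1.19 ± 0.30, Tnfaip3, the ubiquitin-editing enzyme A20, by 1.19 ± 0.44 and its partner Tnip1 by 1.03 ± 0.36. These 4 had an adjusted p of 7.73e-05 to 0.0118, and 7 inhibitors rose by rank aggregation, which added Traf2 (1.23 ± 1.38), Birc2 (0.56 ± 0.65) and Nfkbia (0.46 ± 0.49), each in 2 of 3 clones. Adjusted over the list alone, 0 were called unblocked, 5 blocked and 7 by rank aggregation. As a set the list missed the threshold by fry (adjusted p = 0.698, and 0.0896 with the clone block), and passed it with the block and TMM scaling together (0.0428; camera, adjusted p = 0.184 with an estimated correlation). Camera with its preset correlation called it higher (adjusted p = 1.76e-05), which did not hold with an estimated correlation (adjusted p = 0.406). Blocked rank aggregation called Cyld (adjusted p = 0.0232) and not Birc2 (0.607). The 13 members not called by unblocked rank aggregation were Cyld (0.70 ± 0.37), Nlrp12 (0.47 ± 0.60), Birc3 (0.19 ± 0.19), Usp18 (0.15 ± 0.20), Nlrc3 (0.14 ± 0.30), Tax1bp1 (0.11 ± 0.38), Tollip (0.02 ± 0.11), Tnip3 (-0.05 ± 0.09), Irak3 (-0.10 ± 0.35), Socs1 (-0.13 ± 0.40), Rnf11 (-0.14 ± 0.45), Zc3h12a (-0.14 ± 0.22) and Itch (-0.34 ± 0.22).

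Guides against Tbk1 had the largest rise between the gates among targets called with the block, 2.35 ± 0.66, and those against the related kinase gene Ikbke rose by 0.86 ± 0.07 (blocked adjusted p = 3.66e-04 and 0.0105). They were the 2 of 8 interferon signalling genes called, by the block, by rank aggregation and when adjusted over the list alone. Camera with its preset correlation called this list higher (adjusted p = 3.73e-04), but not with an estimated correlation (adjusted p = 0.406). Pcgf1, which had risen by day 14, was also higher in the bright cells, by 1.68 ± 0.27 (blocked adjusted p = 3.91e-05, rank aggregation 0.0566), as were Cbfb, the partner of RUNX transcription factors (0.95 ± 0.23), and the kinase gene Mapk6 (1.04 ± 0.49). Of 10 TNF and IL-1 signalling genes, 1 fell by the block and by rank aggregation, the TNF receptor gene Tnfrsf1a (-1.43 ± 0.52), and 3 when adjusted over the list alone by each. Blocked rank aggregation added Tnf as higher (0.59 ± 0.07, adjusted p = 0.00581). Of 11 growth suppressors, the phosphatase gene Dusp6 (-1.09 ± 0.38) and Btg1 (-1.01 ± 0.40) fell with the block, and Btg1 by rank aggregation, which with the block called both.

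**Figure D4:**
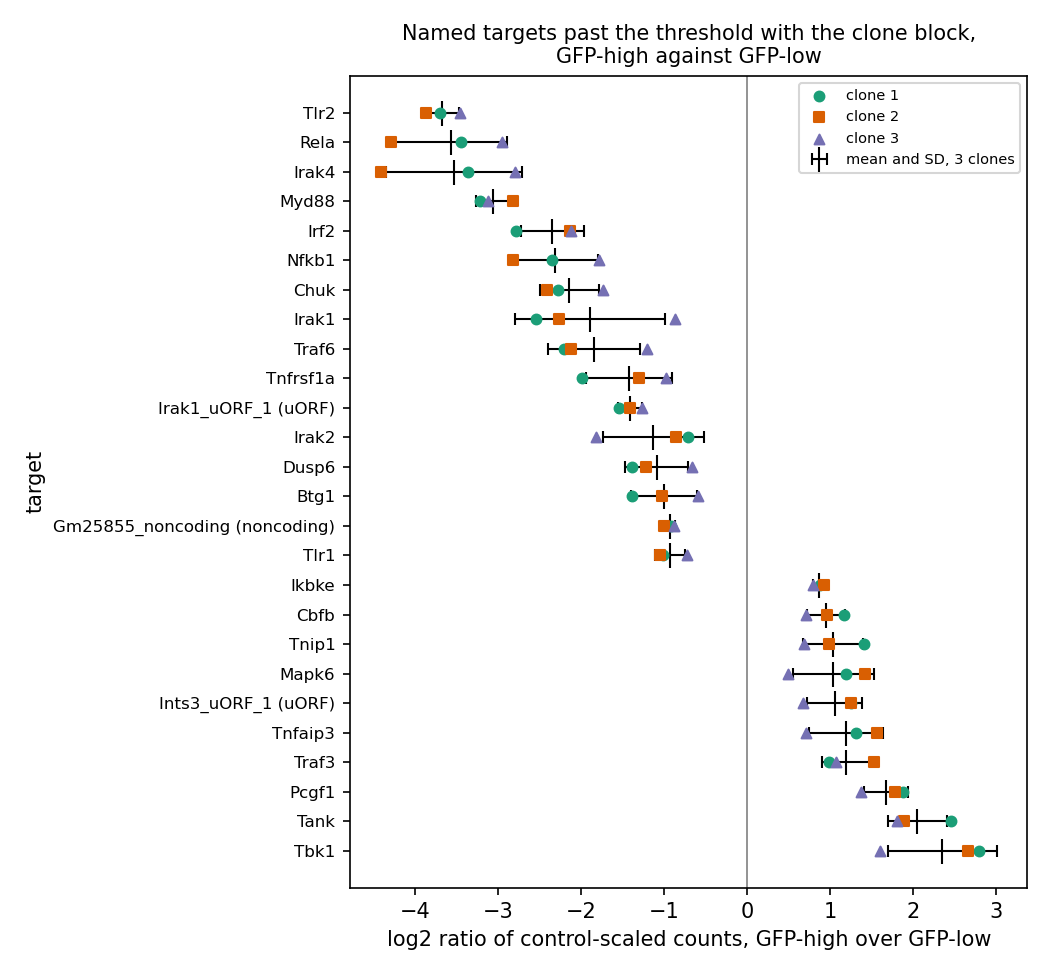
Log2 ratio of control-scaled counts, GFP-high over GFP-low (x axis), for the named targets among the 30 past the threshold with the clone block (y axis). Points are the 3 clones and bars the mean ± SD; Ints3_uORF_1 stands for the joint target of uORFs 1 and 2, and Gm25855_noncoding for its joint target with Snhg1. Tlr2 lies lowest at -3.68 and Tbk1 highest at 2.35, each on the same side of 0 in all 3 clones.

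In essential gene lists rank aggregation made at most 2 calls per list between the gates, and with the clone block it made 0 in the ribosomal, translation, splicing, division and co-activator lists. Unblocked, 2 of 8 translation factors rose, Eif5a among them (1.72 ± 0.59, on 26 ± 8 control-scaled reads in GFP-low and 87 ± 16 in GFP-high), as did 1 of 11 ribosomal protein genes, Rps3 (2.19 ± 2.90, on 11 ± 17 and 28 ± 22 reads). Of 7 splicing genes Srsf2 rose (1.19 ± 1.07), of 3 division genes Cdc16 (0.30 ± 0.56) and of 4 co-activators Ep300 (0.13 ± 0.68). Adjusted over the list alone, rank aggregation called 3 translation factors, 4 ribosomal protein, 1 splicing, 1 division, 2 co-activator, 1 of 2 proteasome, 1 of 12 macrophage identity and 2 growth suppressor genes. None of the 12 mitochondrial respiration genes and not the 1 RNA polymerase gene was called. With the clone block 0 members of these lists except the growth suppressors were called, over all targets or over the list alone. Camera with its preset correlation called ribosomal protein genes higher (adjusted p = 0.00147), but not with an estimated correlation (adjusted p = 0.406). Atg9a (1.18 ± 0.50), Ints3 (1.28 ± 0.30) and Wdr82 (1.34 ± 0.80) rose by rank aggregation and not with the block, in edgeR (adjusted p = 0.169, 0.0977 and 0.745) or in rank aggregation (0.420, 0.933 and 1.00). Their control-scaled reads in GFP-low and GFP-high were 306 ± 259 and 785 ± 640 for Atg9a, 330 ± 244 and 739 ± 416 for Ints3 and 20 ± 10 and 58 ± 47 for Wdr82, and single Ints3 guides ranged from -1.42 to 6.57 in clone 2.

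Of the 3 noncanonical targets called with the clone block, Irak1_uORF_1 moved the most between the gates. Its guides fell by 1.41 ± 0.14 in GFP-high, with log2 ratios of -1.55, -1.42 and -1.27 in the 3 clones (adjusted p = 7.73e-05 with the clone block and 0.00272 by rank aggregation), while guides against the Irak1 CDS fell by 1.89 ± 0.90. All 6 uORF guides were lower over the clones together, but in clone 3 single guides ranged from -1.48 to 1.17, the latter for GCACGAGGCCGGCCTGAAG. In the unblocked fit, where the target was not called, the log2 fold change of Irak1_uORF_1 was 0.04 without the GFP-low library of clone 3. For Irak1_uORF_1, GFP-high against GFP-low, rank aggregation without clone 1 made no call (adjusted p = 0.25), nor did the block with mean or median log2 over guides (log2 fold changes of -1.16 and -1.15, adjusted p = 0.277 and 0.203) or with fry on guides (0.753). Of the 6 spacers, 5 overlap and join into 1 stretch of 33 bases, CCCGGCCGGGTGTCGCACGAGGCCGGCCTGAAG. The sixth, GAGCGCCGCCTCTTCCGCC, had log2 ratios of -1.71, -2.05 and -0.12. Rank aggregation takes guides as independent, so its p for Irak1_uORF_1 may be too small. The genomic positions of the guides, and so their distance from the Irak1 coding sequence, were not analysed here. The blocked fit called 2 further noncanonical targets. A joint lncRNA target of Gm25855 and the small nucleolar RNA host gene Snhg1 fell (-0.94 ± 0.06, 5 of 5 guides, adjusted p = 0.00505) but was not called by rank aggregation (adjusted p = 0.543). The joint target of Ints3 uORFs 1 and 2 rose (1.05 ± 0.33, adjusted p = 0.00222; rank aggregation 1.00, and 0.00301 with the clone block). Shares of called targets among CDS and noncanonical ORFs were 18 of 1224 and 1 of 2091 for falls with the block (Fisher's exact test, 2-sided, adjusted p = 1.12e-06). Guide sets were not matched between these classes either.

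Between the gates, limma called 0 of 1325 pairs of a noncanonical ORF with its CDS (12 at an unadjusted p under 0.05) and 0 of 596 pairs of an ORF with the rest of its lncRNA (0 at an unadjusted p under 0.05). With the clone block it called 3 CDS pairs (on simulated counts this test recovered 98 of 124 changed pairs with 7 false calls), among them Tlr2_uORF_3 (-0.24 ± 0.85) above the Tlr2 CDS (adjusted p = 0.00403) and Traf6_uORF_3 (-0.08 ± 0.23) above the Traf6 CDS (adjusted p = 0.0307). The Irak4 uORF pair, at -0.56 ± 0.58 against -3.53 ± 0.82, missed the threshold (adjusted p = 0.0516). The lncRNA pair with the smallest p with the block, Gm20186_ncORF_2 (-0.61 ± 0.23), had an adjusted p of 0.896. Across pairs the log2 fold changes of the gates correlated between a noncanonical ORF and its CDS (Pearson r = 0.159, Spearman rho = 0.0717, permutation adjusted p = 2.0e-05 and 0.0116). Without clone 2 r was 0.0864 (adjusted p = 0.00240), and rho was not past the threshold without clone 1 or clone 2 (adjusted p = 0.142 for each). No correlation was detected between an ORF and its lncRNA (r = -0.0478, rho = -0.0153, adjusted p = 0.243 and 0.709). Genes with several ORF targets enter several times here too.

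Single guides and control sets gave the background of both comparisons. EdgeR on single guides called 0 of 35980 guides at day 14 (777 at an unadjusted p under 0.05; 1 called with the clone block) and 0 between the gates (71; 40 called with the clone block). Of 150 sets of 10 non-targeting guides, 0 fell past the threshold of the targets in either comparison, with and without the clone block. A sum over 10 guides varies less than one over 6, the median for tested CDS and for noncanonical ORF targets. Unblocked between the gates no target passed either, so the 0 sets there tell little. Irak4, Myd88, Rela and Tlr2, which were the lowest targets called between the gates with the block, were not called over 14 days of growth by edgeR, blocked or not, or by rank aggregation (-0.24 ± 0.20, 0.05 ± 0.16, -0.12 ± 0.46 and -0.02 ± 0.09).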

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

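All tests of the first 2 patterns below, and those on single guides and on upstream cutting for the third, were chosen only after the result was seen; the test on shared spacers was written before. The tests on growth and on read depth of clone 3 replaced 2 earlier ones, and the new tests and their limits were chosen when these or closely related values were already known. Growth was first judged by GFP-high over day 0 in clone 2 (median log2 ratio 0.0505, with 1.20 in GFP-low), then by clones 1 and 3, then by both gates of clone 2 over day 14. Depth was first judged by an SD 14.1 times that of counting alone in clone 3, where clones 1 and 2 also had 4.56 and 5.54, which could not decide. Growth of the cells was the biological explanation tested for the first pattern, and none was tested for the second.

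In the day 14 library of clone 2, 803 of 20453 lncRNA guides, from 264 genes, lay more than 1.5 log2 units above day 0, at a median of 2.34, and their extra reads made up 7.51% of that library. Low read depth would raise uORF guides alike, but the odds ratio of lncRNA against uORF guides above that limit was 6.42. A growth advantage that these guides give would show in the other clones, but their median log2 ratio of day 14 over day 0 was -0.34 in clone 1 and -0.0870 in clone 3. Growth in clone 2 alone is argued against as the whole cause, since over these guides GFP-low lay at a median of -1.24 (SD 0.63) and GFP-high at -2.37 (SD 1.26) log2 units to day 14; picking the guides by their day 14 reads lowers these ratios in part, so a smaller share of growth stays open. Reads from another guide pool in clone 2 libraries stay open as a candidate explanation, since the same guides had a median log2 ratio of GFP-low over GFP-high of 1.14 in clone 2, and -0.22 and 0.08 in clones 1 and 3.

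Non-targeting guides were spread widely in both gates of clone 3. Read depth and chance sampling within each gate act on each gate alone and are argued against by a correlation of 0.843 between the gates, of which noise in the shared day 14 library alone could give at most 0.122. A single outgrown guide behind the Bbc3 guides of clone 3, whose log2 ratios to day 14 were 4.59 in GFP-high and 4.84 in GFP-low, is argued against because 6 of 6 guides lay among the highest 2% of non-targeting guides in both gates. A loss of cells before the gates in clone 3 may be the cause, since the gates shared 83.8% of the variance against day 14, and still at least 71.7% after all variance of day 14 over day 0 was taken off, compared with 21.7% and 56.8% in clones 1 and 2 with nothing taken off.

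Guides against Irak1_uORF_1 fell in the GFP-high gate with the clone block. The fall was not that of 1 guide alone, as 5 of 6 guides were below the median non-targeting guide in all 3 clones. The target was picked on these same guide values and 5 spacers overlap, so this cannot decide on an artifact of 1 site. No spacer was shared with guides against the Irak1 CDS, as the longest shared run was 6 bases. Spacers were compared only with one another and not with the Irak1 sequence, so this cannot decide on cutting within the CDS. Of uORF targets of fallen host genes, 5.26% (1 of 19, Irak1_uORF_1 itself) fell by rank aggregation, so a fall of most such targets was not seen. The 19 came from 12 hosts, and 5 were lower in all 3 clones without regard to calls. Since guide positions were not analysed, this cannot decide on an effect of cutting upstream of a CDS that depends on position. An effect on the Irak1 gene itself, through its promoter or start of transcription, stays open and was not tested, since guide positions were not analysed here. A role of the uORF product may be put forward only as a hypothesis, and 5 of the 6 spacers address a single stretch of 33 bases.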

How the results depend on the processing

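The settings that pair the block or rank aggregation with a second choice, robust dispersion, the class difference between the gates and the correlations without clones were chosen after seeing the data; the others were planned. No value past the threshold of the fixed test reversed, and Irak1_uORF_1, called with the block and by rank aggregation, changed sign in 1 unblocked setting given below. For day 14 against day 0 the fixed test called 2 targets. It called 1 with TMM, DESeq2 size factors, total counts, scaling on noncanonical guides or without each target's most extreme guide, and 0 with all 12 libraries, fry on guides, or median or mean log2. DESeq2 called 69, rank aggregation 187 (179 with at least 6 guides) and random non-targeting sets 659, a method that made 107 false calls on simulated counts. Leaving out clones gave 0 to 73, single libraries 0 to 10, and clones under rank aggregation 85 to 220. No plasmid filter, 50 plasmid reads, at least 6 guides and robust dispersion each gave 2. Between the gates the count of 0 went to 1 with TMM, DESeq2 size factors or total counts, 5 with all 12 libraries, 7 with DESeq2, 254 with random non-targeting sets and 60 with rank aggregation (61 with at least 6 guides). It went to 0 to 6 without clones and 29, 36 and 48 without clones 1, 2 and 3 under rank aggregation.

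With the clone as a block (pairing), day 14 gave 1 target, 1 with TMM or DESeq2 size factors, 18 with total counts, 20 with noncanonical guides, 57 with robust dispersion, 396 with DESeq2, 77 with mean and 85 with median log2, 0 with fry, 474 with random sets, 135 with rank aggregation and 0 to 74 without clones. The gates gave 30 with the block, 29 with robust dispersion, 27 with TMM, DESeq2 size factors or total counts, 30 with noncanonical guides, 53 with DESeq2, 12 with mean and 7 with median log2, 0 with fry, 213 with random sets, 45 with rank aggregation and 17, 70 and 90 without clones 1, 2 and 3. Single guides went from 0 to 1 (day 14) and to 40 (gates) with the block. Lists at day 14 went from 0 to 1 with the block and 0 to 9 without clones; lists of the gates went from 1 to 0 with the block, 2 with TMM, 3 with the block and TMM (TLR2 signalling, NF-kB inhibitors and interferon signalling), and 0 without clones, blocked or not. Pairs of noncanonical ORF against the canonical CDS of the same gene, day 14 against day 0, went from 7 to 135 with the block, 27 with mean log2, 129 with both, 0 to 219 without clones and 28, 46 and 286 without clones 1, 2 and 3 in the block. CDS pairs of the gates went from 0 to 3 with the block, 5 with mean log2 in the block and 1, 15 and 44 without clones 1, 2 and 3 in the block, and lncRNA pairs from 0 to 4 at most in the block without clone 2. The class difference in the share of depleted targets, CDS less noncanonical ORFs, went from 0 to 10.4 percentage points with rank aggregation, 8.86 with rank aggregation in the block and 27.3 with random sets. The class difference in the share of depleted targets, GFP-high against GFP-low, went from 0 to 1.42 with the block, 1.67 with rank aggregation, 1.54 with both and 4.22 with random sets. Correlations across pairs at day 14 with the lncRNA weakened without clone 2 (r = 0.0507, rho = 0.0102) and were at most r = 0.157 without clone 3 and rho = 0.197 without clone 1. With the CDS rho weakened without clone 2 (0.0576) and was at most 0.181 without clone 3. Those of the gates weakened for the CDS by rho without clone 1 (0.0456) or clone 2 (0.0461) and not without clone 3 (0.0709). By r they stayed past the threshold and were lowest without clone 2 (0.0864). For the lncRNA, never past the threshold, they were lowest without clone 2 (r = -0.0533, rho = -0.0427) and turned to r = 0.0325 and rho = 0.00372 without clone 3. Non-targeting sets past the threshold went from 0 to 1 with random sets, with or without the block, 6 with DESeq2 in the block (day 14), and 1 in the block without clone 3 (gates).

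Across named targets and settings, 859 values at day 14 kept their direction and side of the threshold, 244 passed it where the fixed test did not and 37 no longer passed. For the gates the first 2 counts were 759 and 374, and 5 values changed sign without a call. Irak1_uORF_1 went to 0.04 without GFP_low replicate 3. Gm20186_ncORF_2 went to 0.46 and Sar1b_uORF_1 to -0.17, in 1 setting each. St3gal1_uORF_3 went to -0.08 with median log2, blocked or not. The cause was not tested. Selection on guide efficiency was not run, since no score was used here. At a mean of 247 reads per guide, day 14 of clone 2 had the least depth by the mean. By median reads per guide, GFP-low and GFP-high of clone 3 were lower, at 178 and 200 against 217. In these 2 libraries the top 100 guides took 12.5% and 11.9% of the reads.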

Other observations

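The values for Ints3 and for the gates of clone 3 were chosen after the results were seen, and the tests on splits were written before. Rank aggregation in the block, which the splits include, was itself a setting added after the data were seen.

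Guides against the Ints3 CDS were already scarce at day 0, with log2 ratios to the plasmid pool of -1.61, -1.58 and -5.51 in clones 1 to 3. The joint target of Ints3 uORFs 1 and 2 rose by day 14 by rank aggregation (1.29 ± 0.67) and rose in GFP-high with the clone block (1.05 ± 0.33), n = 3. The difference between CDS and uORF guides was not tested across these comparisons.

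Guides against Pcgf1 and Kdm2b, which rose by day 14, and against Bbc3 and Bcl2l11 lay above day 14 in both gates of clone 3, where non-targeting guides had an SD of 1.40 and 1.55. Among the highest 2% of non-targeting guides in both gates were 6 of 6 guides for Bbc3, 2 for Bcl2l11, 1 for Kdm2b and 0 for Pcgf1. Log2 ratios of GFP-high and GFP-low to day 14 in clone 3 were 3.45 and 2.07 for Pcgf1, 3.35 and 2.95 for Kdm2b and 2.87 and 3.20 for Bcl2l11. In clone 1 they were 1.48 and -0.39 for Pcgf1, 0.84 and 0.58 for Kdm2b and 0.48 and 0.43 for Bcl2l11, and in clone 2 they were 2.21 and 0.45, 1.30 and 0.62, and 0.79 and 0.42. These are values without a test.

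The 6 libraries of a comparison make 10 splits into 3 against 3, too few for a share under 0.05, as are the 4 ways to turn labels within clones. At day 14, 1 of 10 splits gave as many targets (real 2, highest other 0), CDS pairs (7 and 0) and rank aggregation calls (187 and 122). For guides, lists and lncRNA pairs it was 10 of 10, with 0 calls in each. Between the gates, 1 of 10 gave as many rank aggregation calls (60 and 35) and lists (1 and 0), and 10 of 10 as many targets, guides, lncRNA pairs and CDS pairs, with 0 in each. Of the 4 ways within clones, 1 gave as many with the block, at 1 and 0 targets for day 14 and 30 and 0 for the gates, and with rank aggregation in the block, at 135 and 42 and at 45 and 8. The day 14 split with 122 rank aggregation calls set day 0 of clones 1 and 2 and day 14 of clone 3 against the rest, so it keeps the real grouping of clones 1 and 2 and turns that of clone 3 alone.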
